A study of Arabidopsis thaliana with 8 samples.

How the data were processed

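E2Fa-bound chromatin was isolated from a PSB-D suspension culture of Arabidopsis thaliana by ChIP, ChAP or TChAP and sequenced. Cells had been fixed 2 days after subculture with 0.75% formaldehyde for 10 min, and the reaction was stopped with 250 mM glycine, per the labels' protocols. The 8 libraries fell into 6 groups, namely ChIP (n = 1), ChAP (n = 1), TChAP (n = 2) and a mock of each (n = 1, 1 and 2). The mock ChIP came from tagged cells and the other mocks from wild-type cells, so the kind of control differs between ChIP and the affinity methods.

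The data used were 3 peak lists, 1 per method, with 3740 rows in all. BWA 0.5.9, MACS 1.3.7 and build TAIR9 are named in the submitters' processing notes, without roles or settings. Peak identifiers in the lists carry a run number from 1 to 100, per the files themselves, and the TChAP list is described there as an overlap of replicates. The rules by which runs and replicates were combined are not given in the sources used here. Each list gives 1 peak per assigned gene, with its position, sequence, the region classes it touches and the distance of its centre to the start codon. The score of each peak is the authors' deposited value from the peak caller. Its scale is not stated, it reached 3233 in TChAP with 13 peaks at exactly 3100, and it was used to rank and describe peaks within a list and to correlate shared peaks between lists, not to compare levels between methods. The largest share of a peak in 1 region class was deposited as a fraction and was not used further. Whether mock libraries were subtracted in the same way for each method is not given in the sources used here. The combination into 1 list per method means that replicates cannot be compared, that a threshold decides which genes appear, and that a peak between genes is credited to 1 of them.

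Peak lists were analysed as given. All peaks were on the 5 nuclear chromosomes. Overlap required at least 1 bp and was checked with bedtools 2.31.1. Chance overlap came from 1000 random placements of each peak within its chromosome, up to the last listed position. Gene overlap used Fisher's exact test over the 37899 nuclear loci of the reference table (assembly TAIR10.1), which was used for names, gene classes and gene order only. It held 410 of 415, 908 of 918 and 2386 of 2407 assigned genes. The 8 gene lists (178 genes of 7 functional lists and 20 photosynthesis genes as a control) were fixed before the data were examined. One planned member was dropped because the reference gives its identifier the symbol of another list member. Enrichment used a one-sided Fisher's exact test with 27444 protein-coding genes as background and Benjamini-Hochberg adjustment over 24 tests. All lists were fixed from textbook knowledge of the cell cycle, part of which rests on E2F studies, so they are not blind to E2F biology.

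The planned motif background, random placement in the genome, was replaced, because no genome was used here. The peak sequences in the lists were scanned on both strands in their central 500 bp, and each was shuffled 20 times with its dinucleotide counts kept. The outer parts of the same peaks served as a second background. The chance level of peak positions relative to genes was not analysed here for the same reason. Distances were checked against the sequences: an ATG lay at the stated distance from the centre in 97.8%, 90.0% and 89.4% of ChIP, ChAP and TChAP peaks of coding genes that should contain it, against 13.9%, 10.8% and 12.0% at a random distance. The 5′ or 3′ mark in the lists is not explained there, and of peaks marked 5′ with a located start codon, 30.8%, 39.4% and 37.0% had their centre downstream of it, so the mark was not read as the side of the start codon. The side was read from the located start codons, a choice made after the data were seen. Intervals of shares are exact binomial (Clopper-Pearson) intervals at 95%. They cover counting error only, and peaks are not replicates. Correlations were across shared peaks, and score differences were compared with 10000 random lists of the same size.

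Named genes were chosen by a rule set before the data were examined. They are the 10 genes with the lowest sum of ranks among genes in all 3 lists, the 5 genes with the highest peak among genes of each list alone, all members of the E2F, DP and RBR family, and of each other fixed list up to 5 members in all 3 lists by rank sum and up to 2 members in TChAP alone by score. Ties went to the lower identifier.

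Procedures were tested on simulated data. Of 415 simulated ChIP-sized peaks with 249 planted overlaps in a TChAP-sized list, 251 were found to overlap. An enrichment of 10 in 27 genes in the TChAP list over 27444 genes was called. This was 1 fixed calculation repeated 200 times, so it checks the arithmetic only. Of 200 random lists, 3 were called. All 166 sites planted in shuffled ChIP peaks were found, which checks the search only, since the planted sequence matches the motif. Alternatives were the upper part of each list by score, the 415 highest peaks of each, overlap of at least 50% of the shorter peak or centres within 200 bp, a window of 200 bp, the stricter motif, a 500 bp limit to the start codon, and others added later. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.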

Results

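E2Fa is a transcription factor that pairs with DP proteins and binds promoters of genes used at the start of DNA replication. Its binding sites were mapped in PSB-D, a cell suspension of Arabidopsis thaliana Landsberg erecta that grows in the dark and divides actively. The cells carried E2Fa under the 35S promoter with an HBH tag, which joins histidine stretches, held by nickel beads, to a biotinylated stretch, held by streptavidin. Chromatin crosslinked with 0.75% formaldehyde for 10 min was isolated in 3 ways. ChIP used an antibody against E2Fa, ChAP used streptavidin beads in 1 step, and TChAP used nickel beads followed by streptavidin beads. The samples were 1 ChIP, 1 ChAP and 2 TChAP libraries, with 1 mock ChIP library from the tagged cells and 1 mock ChAP and 2 mock TChAP libraries from wild-type cells. The study was set up to compare the isolation methods on the same factor. The values analysed were 1 list of peaks per method, 1 peak per assigned gene, with a peak-caller score that is the authors' own. Read depth was unknown, and the lists held no value per replicate. No difference between methods could therefore be set against the spread between replicates, and the exact (Clopper-Pearson) 95% intervals given for shares cover counting error only. Coordinates are those of the lists, on build TAIR9.

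Of the 10 genes with the highest-ranked E2Fa peaks by score across all 3 lists, 6 belong to the DNA replication machinery. MCM7 (AT4G02060), MCM5 (AT2G07690), MCM4 (AT2G16440) and MCM2 (AT1G44900), subunits of the replicative helicase, were 4 of the 10 genes with the lowest sum of ranks, together with RPA14A (AT3G52630), a subunit of the protein that coats single-stranded DNA, and PCNA1 (AT1G07370), the sliding clamp of the DNA polymerases. The other 4 were AT1G54300, AT3G12290, AT3G23740 and AT4G14120. The MCM7 peak was the highest in ChIP, with a score of 1996, on chromosome 4 from 901084 to 901843. It spanned intergenic, UTR, coding and intron sequence, and its centre lay 21 bp from the start codon. In ChAP the highest peak, with a score of 2518, was assigned to AT3G12290 and lay on chromosome 3 from 3918801 to 3919895. AT3G12290 is the immediate neighbour of RBR1 (AT3G12280), the retinoblastoma-related protein that binds E2F factors, and RBR1 itself was assigned no peak in any list. The MCM5 peak had ranks of 3 in ChIP and 4 in ChAP. In TChAP 13 peaks, 7 of the 10 genes' peaks among them, shared a score of exactly 3100, so the order among them was not resolved. Whether 3100 is a limit of the scale is not stated, so the rank of these peaks among the highest TChAP peaks, and with it the choice of the 10 genes by rank sum, is also uncertain.

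TChAP listed the most E2Fa peaks, 2407, against 918 for ChAP and 415 for ChIP, and each peak was assigned to a gene of its own. Of the ChIP peaks, 89.4% (371 of 415, interval 86.0 to 92.2%) overlapped a TChAP peak by at least 1 bp, and 75.7% (314 of 415, interval 71.2 to 79.7%) overlapped a ChAP peak. Of the ChAP peaks, 72.1% (662 of 918, interval 69.1 to 74.99%) overlapped a TChAP peak. Random placement of the same peaks gave a mean of 10.2, 4.12 and 23.4 overlaps, and none of 1000 placements reached the observed number (one-sided permutation p = 0.001 for each pair, the smallest the placements can give). The placements were uniform along each chromosome, while most peaks lay close to start codons. They do not give the chance overlap of peaks kept to promoters. In the other direction, 1654 TChAP peaks (68.7%, interval 66.8 to 70.6%), 225 ChAP peaks (24.5%, interval 21.8 to 27.4%) and 13 ChIP peaks (3.13%, interval 1.68 to 5.30%) overlapped no peak of another list. With only the 415 highest peaks of each list, 64.1% of the ChIP peaks overlapped a TChAP peak and 61.2% a ChAP peak.

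At the level of genes, 283 were in all 3 lists, 1656 in TChAP only, 225 in ChAP only and 16 in ChIP only, out of 2677 in any. Among the 37899 nuclear loci of the reference, ChIP and ChAP shared 309 genes where 9.82 would be shared by independent lists, ChIP and TChAP 366 against 25.8, and ChAP and TChAP 658 against 57.2 (Fisher's exact test, two-sided, p at most 1e-300 for each). These are 31.5, 14.2 and 11.5 times chance, and with protein-coding genes only the values were 24.1, 10.9 and 8.89. Genes listed by ChIP and ChAP and absent from the TChAP list used here numbered 29. They included ETG1 (AT2G40550), an MCM-binding replication factor, at rank 4 in ChIP and 3 in ChAP, with its ChIP peak on chromosome 2 from 16934472 to 16935232. The chromatin remodeller gene CHR17 (AT5G18620), at rank 10 in ChIP and 2 in ChAP, was another. ETG1 and CHR17 are named here after their values were seen.

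The highest peak among genes of the ChIP list alone was that of GATA17 (AT3G16870), a transcription factor gene, with a score of 353 and rank 130. COM1 (AT3G52115), needed for DNA end resection, followed at rank 141, then RL1 (AT4G39250), UBC20 (AT1G50490) and AT1G61415. Among genes of the ChAP list alone, the homeobox gene ANL2 (AT4G00730) had the highest peak, with a score of 788 and rank 31, on chromosome 4 from 299087 to 300419, and its centre lay 12 bp from the start codon. The others were AT3G53640, AT2G42720, the histone H2A gene HTA10 (AT1G51060) and AT2G15630, at ranks 116 to 183. None of the 5 ChAP peaks held the E2F sequence TTTSSCGC, described below, in its central 500 bp, the only part searched. Among genes of the TChAP list alone, AT4G39240 led with a score of 1747 at rank 135, on chromosome 4 from 18270860 to 18271306. That peak covers the ChIP peak assigned to RL1, at 18270928 to 18271274, so the same bound segment was given to different neighbours in the ChIP and TChAP lists. MBD10 (AT1G15340), a gene of the methyl-CpG-binding domain family, AT1G72200, PLA-I{gamma}1 (AT1G06800) and AT5G61865 followed at ranks 164 to 184.

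Peaks found by more than 1 method had higher scores than peaks of 1 method alone, within each list. The median score of shared against unshared peaks was 772 against 243 in TChAP, 148 against 86.6 in ChAP and 233 against 154 in ChIP. The median of the shared peaks lay above all of 10000 random lists of the same size in TChAP and ChAP and at percentile 98.7 in ChIP, as a description of these lists. Across peaks assigned to the same gene, scores of different methods rose together, with a Spearman's rho of 0.84 over 311 peaks for ChIP and ChAP, 0.87 over 370 peaks for ChIP and TChAP, and 0.82 over 654 peaks for ChAP and TChAP. Pearson's r of the log2 scores was 0.86, 0.84 and 0.82 in the same order. These coefficients are across peaks, which are not independent replicates, and no p is given.

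Most genes of replication origin licensing and of the replicative helicase were bound in each list. Of 27 members, 18 were in the ChIP list, 19 in ChAP and 21 in TChAP, against 0.376, 0.852 and 2.22 members by chance, and 17 were in all 3. Besides MCM2, MCM4, MCM5 and MCM7, the 5 leading members included MCM3 (AT5G46280), with scores of 1129 in ChIP and 913 in ChAP. CDT1B (AT3G54710), which loads the helicase, and MCM9 (AT2G14050) were in TChAP alone, at ranks 864 and 1390. Genes of the replication fork and of nucleotide synthesis gave 24, 21 and 27 of 36 members in ChIP, ChAP and TChAP. RPA14A, PCNA1, PCNA2 (AT2G29570) and the DNA polymerase alpha genes POLA1 (AT5G67100) and POLA2 (AT1G67630) led them, with ChIP ranks from 5 to 18. RPA14B (AT4G18590) and RPA70C (AT5G45400), paralogues of single-strand binding subunits, were in TChAP alone, at ranks 774 and 1519. The adjusted p of the licensing list was 1.29e-26 in ChIP, 3.50e-22 in ChAP and 1.05e-17 in TChAP, and that of the fork list 3.49e-35, 5.09e-22 and 9.03e-22 (one-sided Fisher's exact test, Benjamini-Hochberg over 24 tests, 27444 protein-coding genes as background).

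**Figure D1:**
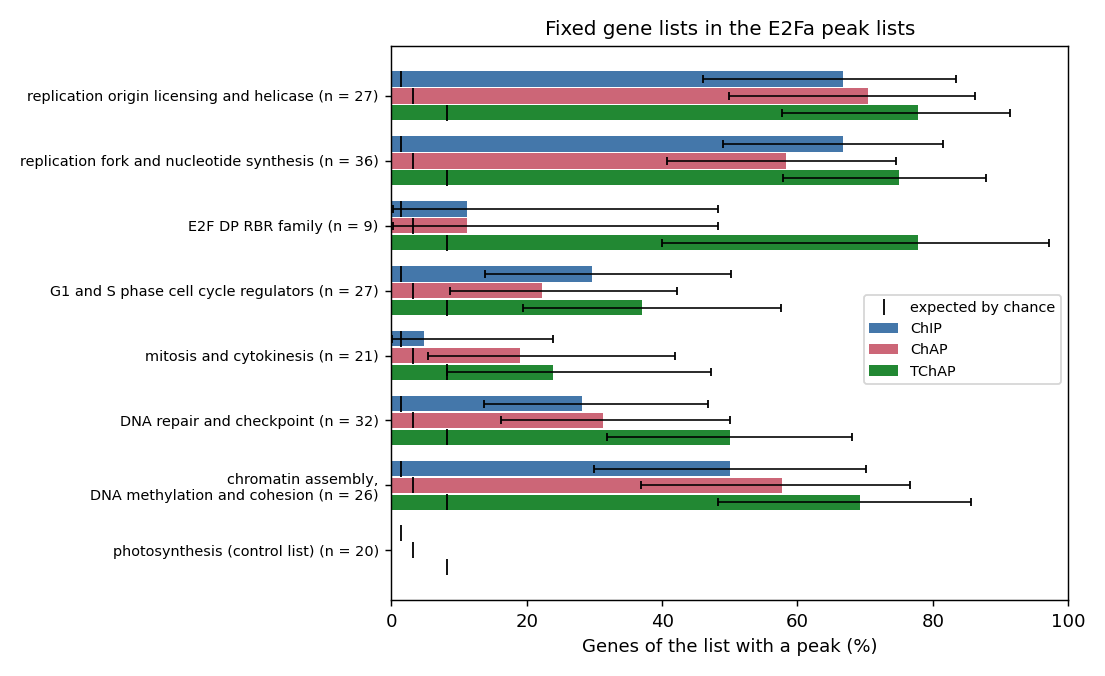
Share of the genes of each fixed list (n genes, in percent) that were assigned a peak in the ChIP, ChAP and TChAP lists, with exact 95% intervals as lines (none drawn for a share of 0) and the share expected by chance as a black tick. In TChAP the licensing list and the E2F family reached 77.8% each, and the photosynthesis control list 0% in all 3.

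Genes of chromatin assembly, DNA methylation and cohesion were also bound in large part, with 13, 15 and 18 of 26 members in ChIP, ChAP and TChAP and adjusted p of 1.82e-17, 4.56e-16 and 5.86e-14. FAS1 (AT1G65470) and FAS2 (AT5G64630), subunits of the histone chaperone CAF-1, the histone methyltransferase gene ATXR6 (AT5G24330) and the DNA methyltransferase genes CMT3 (AT1G69770) and MET1 (AT5G49160) were in all 3 lists. The histone H3 gene HTR1 (AT5G65360) and the cohesin gene SMC1 (AT3G54670) were in TChAP alone, at ranks 682 and 874. Of the DNA repair and checkpoint genes, 9, 10 and 16 of 32 were listed by ChIP, ChAP and TChAP (adjusted p = 9.06e-10, 5.89e-08 and 1.48e-09, Fisher's exact test). The mismatch repair genes MSH6 (AT4G02070) and PMS1 (AT4G02460), SMC6B (AT5G61460) and BRCA1 (AT4G21070) were among those in all 3, with ChIP scores of 721, 364, 389 and 326. RAD17 (AT5G66130), a checkpoint clamp loader, and FANCD2 (AT4G14970), of the interstrand crosslink repair pathway, were in TChAP alone, at ranks 253 and 446.

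Regulators of G1 and S phase were bound in part. ChIP listed 8, ChAP 6 and TChAP 10 of 27 members (adjusted p = 4.62e-09, 0.000244 and 4.97e-05, Fisher's exact test). The cyclin gene CYCA3;1 (AT5G43080), the kinase gene CDKB1;1 (AT3G54180) and the cyclin-dependent kinase inhibitor genes SMR7 (AT3G27630), KRP3 (AT5G48820) and SMR4 (AT5G02220) were in all 3 lists, at ChIP ranks 83 to 336. CYCD5;1 (AT4G37630) and the kinase gene WEE1 (AT1G02970) were in TChAP alone, at ranks 1056 and 1155. Of the mitosis and cytokinesis genes, 1, 4 and 5 of 21 were listed by ChIP, ChAP and TChAP (3.42-fold, 6.04-fold and 2.90-fold, adjusted p = 0.292, 0.00542 and 0.0331, Fisher's exact test). CYCB1;3 (AT3G11520), a mitotic cyclin gene, was the 1 member in all 3 lists, and CYCA1;1 (AT1G44110) and CDC20.1 (AT4G33270) were in TChAP alone, at ranks 1024 and 2387. In the upper part of each list by score the mitosis result did not pass the threshold in Fisher's exact test in ChAP (2.98-fold, adjusted p = 0.344) or in TChAP (3.44-fold, adjusted p = 0.0770). Over all 4 alternatives the adjusted p ranged from 0.0464 to 0.344 in ChAP and from 0.0399 to 0.765 in TChAP. None of the 20 photosynthesis genes, the control list, was in any list, where TChAP would hold 1.64 by chance. The one-sided Fisher's exact test asks only about enrichment, and with so few members expected an empty list says little about specificity.

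Of the E2F family itself, TChAP listed 7 of 9 genes, ChIP 1 and ChAP 1 (adjusted p = 1.32e-06, 0.150 and 0.292, Fisher's exact test). DEL1 (AT3G48160), an atypical E2F that represses entry into the endocycle, was the 1 member in all 3 lists, with scores of 804 in ChIP, 643 in ChAP and 2663 in TChAP. Its ChIP peak lay on chromosome 3 from 17783303 to 17783827, with the centre 76 bp from the start codon. E2FA (AT2G36010) was in TChAP alone, at rank 642, on chromosome 2 from 15119399 to 15120031, 27 bp from its start codon. Its peak spanned intergenic, UTR, coding and intron sequence and held no E2F consensus in the central 500 bp. The E2FA coding sequence is also present in these cells as the tagged transgene. E2FB (AT5G22220), E2FC (AT1G47870), DPA (AT5G02470), DEL2 (AT5G14960) and DEL3 (AT3G01330) were likewise in TChAP alone, at ranks 760 to 2282. DPB (AT5G03415) and RBR1 were assigned no peak. With the 415 highest peaks of each list, TChAP held 1 of the 9 genes, as did ChIP and ChAP. The enrichment in TChAP then did not pass the threshold (7.68-fold, adjusted p = 0.164, Fisher's exact test). Over all 4 alternatives the adjusted p in TChAP ranged from 1.38e-06 to 0.164.

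E2Fa peaks lay close to start codons in every list. The centre was within 1 kb of the start codon, with the lists' mark 5′ for the assigned gene, for 81.4% of ChIP peaks (interval 77.4 to 85.1%), 78.9% of ChAP peaks (interval 76.1 to 81.5%) and 73.0% of TChAP peaks (interval 71.2 to 74.8%). The mark does not give the side of the start codon on which the centre lies. Where the start codon could be located in the peak sequence, the centre lay upstream of it in 68.8% of ChIP peaks (137 of 199, interval 61.9 to 75.2%), 60.8% of ChAP peaks (282 of 464, interval 56.2 to 65.2%) and 62.7% of TChAP peaks (643 of 1026, interval 59.6 to 65.6%). The median distance to the start codon was 148 bp in ChIP, 154 bp in ChAP and 182 bp in TChAP. Peaks that touched no intergenic sequence made up 4.34% of the ChIP list (interval 2.59 to 6.77%), 14.2% of ChAP (interval 12.0 to 16.6%) and 12.4% of TChAP (interval 11.1 to 13.8%). Among the leading genes, the peaks of MCM7, MCM5, MCM4 and MCM2 spanned intergenic, UTR and coding sequence, whereas the ChIP peak of MET1 stayed in intergenic and UTR sequence, with its centre 353 bp from the start codon. Of ChAP peaks in no other list, 24.4% lay wholly within genes, against 16.6% of those shared with TChAP but not with ChIP and 4.24% of ChAP peaks in all 3 lists. Of TChAP peaks in no other list, 13.2% lay wholly within genes.

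The E2F consensus WTTSSCSS (W is A or T, S is C or G) was present in the central 500 bp of 75.4% of ChIP peaks (313 of 415, interval 71.0 to 79.5%), 59.2% of ChAP peaks (543 of 918, interval 55.9 to 62.4%) and 57.9% of TChAP peaks (1394 of 2407, interval 55.9 to 59.9%). The same sequences shuffled with their dinucleotides kept gave 35.2%, 32.9% and 32.2%, and the highest of 20 shuffles gave 39.0%, 35.5% and 33.7%. The stricter form TTTSSCGC was present in 47.7% of ChIP, 27.7% of ChAP and 27.2% of TChAP peaks, against 5.83%, 5.41% and 5.33% after shuffling. In their central 500 bp, the peaks of MCM7, MCM5, MCM4, MCM2, RPA14A, AT3G12290, AT3G23740 and AT4G14120 held TTTSSCGC in all 3 lists, and those of PCNA1 and AT1G54300 in none. The PCNA1 peaks held the wider consensus WTTSSCSS there in all 3 lists, and the AT1G54300 peaks held neither form. Sites of this form were 2.99 times as dense in the central 200 bp as in the rest of the peak in ChIP, 3.25 times in ChAP and 3.05 times in TChAP. Among the 415 highest peaks of each list the shares were 47.7%, 40.2% and 44.6%. No difference passed the threshold after adjustment (two-sided Fisher's exact test over 6 comparisons, adjusted p = 0.0538 for ChIP and ChAP with a raw p of 0.0358, 0.403 for ChIP and TChAP, and 0.279 for ChAP and TChAP). The test treats the lists as independent, although 61.2 to 68.4% of these peaks overlapped between lists, so it does not show that the shares are equal.

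**Figure D2:**
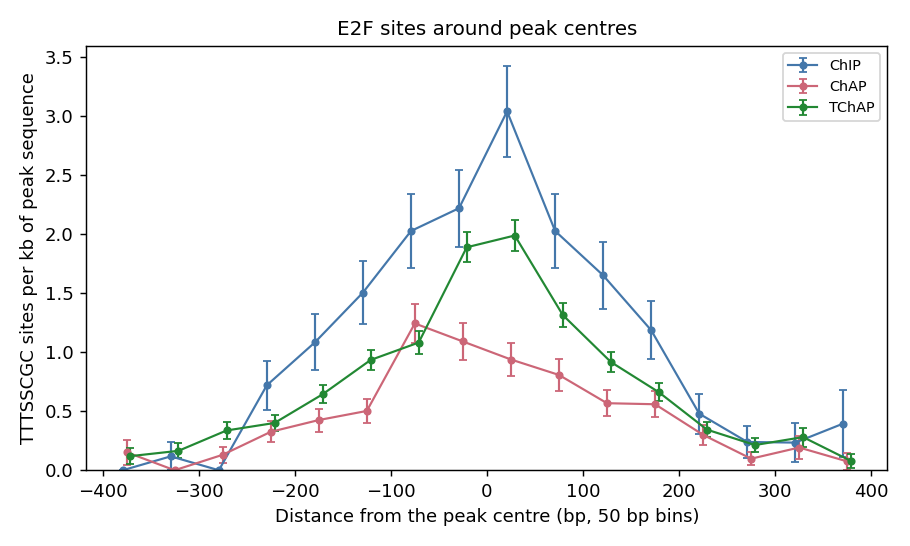
Density of TTTSSCGC on either strand (sites per kb of peak sequence) against the distance from the peak centre (bp, bins of 50 bp) in the ChIP, ChAP and TChAP lists, with bars of the counting error (the square root of the number of sites, per kb). Each list is densest within 100 bp of the centre, at up to 3.04 sites per kb in ChIP, 1.24 in ChAP and 1.99 in TChAP.

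In each list, the share with the E2F site was highest in peaks found by all 3 methods. Its interval overlapped those of peaks shared by ChIP and ChAP only or by ChIP and TChAP only, and these differences were not tested. Of TChAP peaks in all 3 lists, 49.3% held TTTSSCGC (140 of 284, interval 43.3 to 55.3%), against 24.1% of TChAP peaks in no other list (398 of 1654, interval 22.0 to 26.2%; adjusted p = 4.06e-16, two-sided Fisher's exact test). Of ChAP peaks in no other list, 8.89% held it (20 of 225, interval 5.51 to 13.4%), below the TChAP peaks in no other list (adjusted p = 9.70e-08) and below the ChAP peaks shared with TChAP but not with ChIP, at 21.4% (81 of 379, interval 17.4 to 25.8%; adjusted p = 9.08e-05, Fisher's exact test). TChAP peaks shared with ChAP but not with ChIP held it in 20.8% (79 of 380, interval 16.8 to 25.2%). Those shared with ChIP but not with ChAP held it in 41.6% (37 of 89, interval 31.2 to 52.5%). Of ChIP peaks in all 3 lists, 50.5% held it (interval 44.5 to 56.5%). The share was 45.2% (interval 27.3 to 64.0%) for ChIP peaks shared with ChAP only and 42.0% (interval 31.6 to 53.0%) with TChAP only. ChIP peaks in no other list held it in 30.8% (interval 9.09 to 61.4%). Shuffled sequences of the ChAP peaks in no other list gave 5.58%. The share with TTTSSCGC fell with score in each list, in TChAP from 39.9% of the 602 highest peaks to 18.9% of the 602 lowest. TChAP peaks in all 3 lists had a median rank of 177.5, against 1536.5 for those in no other list. Their contrast therefore also sets high against low peaks, and was not tested within strata of score. In the upper part of the list by score its odds ratio was 2.45 (p = 4.68e-09, Fisher's exact test), against 3.07 for all peaks. Among peaks of the upper part of each list by score, the difference from ChAP peaks in no other list did not pass the threshold for TChAP peaks in no other list (odds ratio 2.27, p = 0.0682) or for ChAP peaks shared with TChAP (odds ratio 1.74, p = 0.288, Fisher's exact test).

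**Figure D3:**
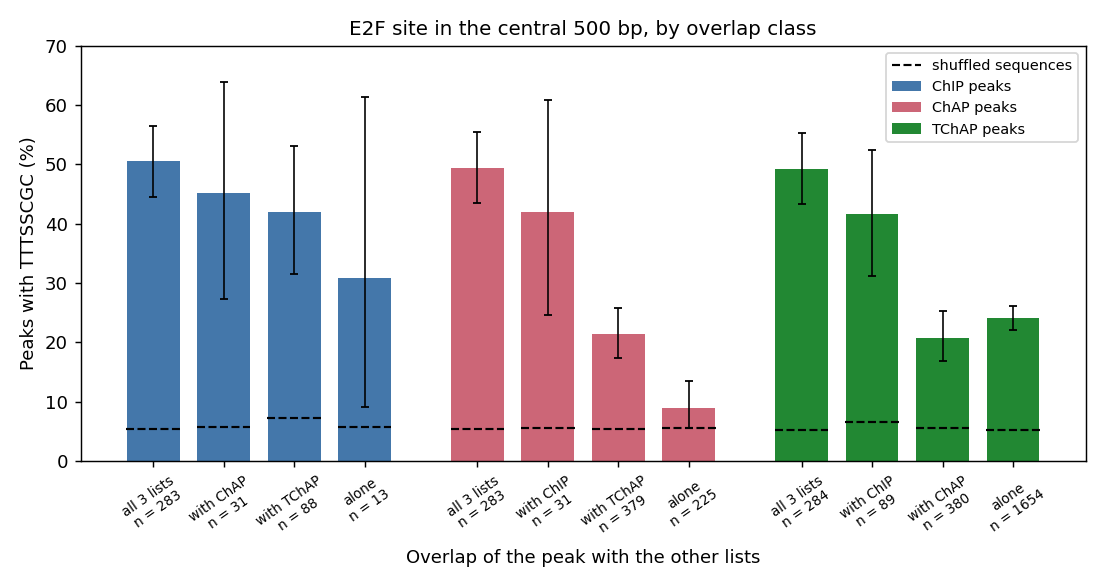
Share of peaks with TTTSSCGC in the central 500 bp (percent, exact 95% intervals as lines) for ChIP, ChAP and TChAP peaks divided by the lists they overlap, with the mean of 20 shuffles as dashed lines and n peaks under each bar. Peaks in all 3 lists lie between 49.3 and 50.5%, and ChAP peaks in no other list at 8.89%.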

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

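The tests with peak edges as background, with neighbours or only motif-bearing peaks counted, with a protein-coding background and with equal lengths for the motif, and the motif odds ratios between overlap classes, were chosen after the data were seen. Of the values that answer a comparison, 143 kept their direction and their side of the threshold, or stayed within their interval, and the others are given here. The 143 include settings that removed nothing, such as nuclear chromosomes in every list and equal lengths in ChIP. Ranks of single named genes cannot change when a list is shortened by score, so they say nothing about stability. Overlap of peaks between methods, overlap of genes, the E2F motif against shuffled sequence and enrichment of 5 of the 8 gene lists (licensing, fork, G1 and S phase, repair and chromatin) kept their direction and their side of the threshold under every alternative run, and with at least 50% of the shorter peak shared the score differences were 79.3, 61.2 and 530 for ChIP, ChAP and TChAP. Peak overlap ranged from 61.2 to 86.5% for ChIP in ChAP, 64.1 to 89.4% for ChIP in TChAP and 68.4 to 83.9% for ChAP in TChAP. By construction, the upper part of each list by score held 208 ChIP, 459 ChAP and 1204 TChAP peaks, and equal lengths left 415 in ChAP and TChAP. Without the 5% highest peaks of either list Spearman's rho fell to 0.77 for ChIP and ChAP, 0.70 for ChIP and TChAP, and 0.71 for ChAP and TChAP, over a narrower range of scores. This removed more than 5% of the shared peaks, leaving 265 of 311, 257 of 370 and 539 of 654 in the same order. For centres of peaks marked 5′, a limit of 500 bp in place of 1 kb gave 73.0% of ChIP, 70.6% of ChAP and 63.5% of TChAP peaks. The mitosis list was enriched 2.98-fold in ChAP and 3.44-fold in TChAP in the upper part by score, 3.30-fold and 3.29-fold at equal lengths, and 5.15-fold and 1.01-fold when only peaks with WTTSSCSS were counted, none past the threshold; in ChIP, where it was not called, its fold was 0 in the upper part and 0 with WTTSSCSS, because its 1 member dropped out. The E2F family in TChAP was enriched 7.68-fold at equal lengths, where fewer peaks were tested. In the upper part by score the odds ratio of TTTSSCGC was 2.27 for TChAP alone against ChAP alone and 1.74 for ChAP with TChAP against ChAP alone, with fewer peaks tested. Otherwise the cause was not tested. Taking only the nearest gene gave no distinct value, since each peak already had 1 gene, and the score was the only value used to rank peaks. Leaving out genes that share a peak with a divergent neighbour was not run, since gene strand was not used here. No paired analysis was possible because each list holds 1 value per peak and no replicate column, and for the same reason no TChAP replicate could be left out. Depth was unknown, so differences in list length between methods cannot be corrected for it.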

Other observations

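The tests in this part on genes of single overlap classes, on peaks missing from TChAP, on base composition and carry-over in ChAP peaks and on the sequence after the start codon were chosen after the result was seen, as was the extension of the G-box test from TChAP, unadjusted, to all 3 lists. Genes of each overlap class were compared with all protein-coding genes for the fixed lists they held (one-sided Fisher's exact test, 32 tests adjusted together), and no class was tested against another. The 283 genes in all 3 lists held 17 of 27 licensing genes and 21 of 36 fork genes, at 65.2 and 60.4 times the number by chance. Genes in TChAP only held 6 of 9 E2F family members, 11.9 times chance (adjusted p = 1.45e-05, exact test), and 8 of 32 repair genes, 4.45 times chance (adjusted p = 0.00140). Licensing and fork genes, 3 of each, were in TChAP only at 1.98 and 1.48 times chance (adjusted p = 0.384 and 0.560, exact test). Genes in ChAP and TChAP but not ChIP held 4 of 26 chromatin genes (adjusted p = 0.00149) and 3 of 32 repair genes (adjusted p = 0.0314, exact test). Genes in ChAP only held 1 mitosis gene, CDKB2;1 (AT1G76540), and 1 chromatin gene, HTR9 (AT5G10400), and no member of the other 6 lists.

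Of the 314 ChIP peaks shared with ChAP, 31 had no counterpart in the TChAP list used here, among them those of ETG1, CHR17, UVI4 (AT2G42260) and MSH7 (AT3G24495); none of their genes had another TChAP peak, and 7 had an immediate neighbour with one. A ceiling of the TChAP score stays open for missing peaks at ChIP ranks up to 209, because ChIP rank does not show which reached the highest TChAP scores. ORC3 (AT5G16690), at ChIP rank 85, scored 3100 in TChAP, and MCM8 (AT3G09660), at ChIP rank 96, scored 3165. For the missing peaks at ChIP ranks 214 to 382, scores of listed genes argue against a ceiling. Fixed-list members at ChIP ranks 210 (MET1) to 411 (TK1A) that TChAP also listed scored 285 to 1413 there, far below 3100. Genes outside the fixed lists were not compared. Of the 50 highest ChIP peaks 10% were missing (interval 3.33 to 21.8%), and of the 264 lower ones 9.85% (two-sided Fisher's exact test, p = 1). The cut at 50 was chosen after the data were seen. The 5 missing above it lay at ranks 4 to 19, and the next lay at rank 53. Against unspecific binding, 45.2% of the missing peaks held TTTSSCGC (interval 27.3 to 64.0%), where the highest of 20 shuffles gave 12.9%. Loss of wide peaks when runs or replicates were combined stays open as a candidate explanation, since the missing ChIP peaks were longer, with a median of 704 bp against 596 bp for peaks in all 3 lists (two-sided permutation p = 0.0205, and 0.00742 with the trend of length with score removed, a condition added once the first p was known). By ChAP lengths the difference was 773 against 673 bp (permutation p = 0.0635), and no biological explanation was tested.

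ChAP peaks in no other list held TTTSSCGC in 8.89%, where shuffling gave 5.58%. Lower scores argue against being the whole cause, since within 10 strata of the ChAP score the share stayed 10.4 percentage points below that of ChAP peaks shared with TChAP only (one-sided permutation p = 0.0003), though among the upper part by score, with fewer peaks, the odds ratio of 1.74 had an exact p of 0.288. Base composition does not account for it either, as the observed share was 1.59 times the shuffled one (interval 0.989 to 2.40) against 4.60 times (interval 4.21 to 5.01) in TChAP peaks alone. Carry-over of unrelated chromatin on streptavidin may contribute and stays open, because the interval of 5.51 to 13.4% includes the shuffled share, but the observed share lay above the highest of 20 shuffles, 8.44%, so it need not hold for all these peaks. No biological explanation was tested.

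Of the 178 genes of the 7 functional lists, 65 were assigned no peak in any list. For RBR1 and CDC6A (AT2G29680) a neighbour was listed, AT3G12290 in all 3 lists and AT2G29679 in ChIP and ChAP. Each of these peaks held TTTSSCGC in its central 500 bp. RBR1's other neighbour PRMT3 (AT3G12270) was listed without it there in ChIP and TChAP. Assignment of a peak to 1 gene may hide members, and 16 of the 65 had a listed immediate neighbour against a mean of 10.9 in random genes without a peak (one-sided permutation p = 0.0685 over 10000 draws). For 11 of the 16 no neighbour's peak held TTTSSCGC in its central 500 bp. This misses the threshold, so for the lists as a whole it cannot be told apart from chance neighbours, while the planned prediction concerned the whole set and not these 2 genes.

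The G-box CACGTG was 2.21, 2.09 and 1.88 times as dense in the central 200 bp as outside in ChIP, ChAP and TChAP peaks. The hypothesis that peaks without an E2F consensus may be bound through other promoter factors predicted more G-boxes there. In ChIP, 18.6% of 102 peaks without WTTSSCSS held a central G-box against 7.67% of 313 peaks with it (adjusted p = 0.00804, two-sided Fisher's exact test over 3 lists). In ChAP the shares were 16.3% and 11.4% (adjusted p = 0.0576, unadjusted 0.0384) and in TChAP 12.2% and 9.97% (adjusted p = 0.0853, the same unadjusted), which do not pass the threshold after adjustment in the exact test.

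In 1026 TChAP peaks whose start codon could be located in the peak, the core GCGGGA on either strand was found 1.25 times per kb in the 200 bp before the start codon and 0.636 times per kb in the 200 bp after it. The most frequent single position was directly behind the start codon, in 10 peaks, where the next position had 4. Codon use cannot be told apart from any other reason for this. The codon GGA followed in 6.54% of 153 sequences starting with ATGGCG and in 2.88% of 868 other starts (two-sided Fisher's exact test, p = 0.0298). This comparison replaced an earlier one with shuffled sequences, in which 10 sites stood against a highest of 5 in 20 shuffles, because shuffling breaks up the frequent start ATGGCG. Neither comparison is independent of the observation, since both count the 10 sites that prompted them in peaks already selected for E2Fa binding, and genes without a peak were not compared.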
